A study of Homo sapiens with 12 samples.

How the data were processed

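RNA was measured in 2 established human papillary thyroid cancer cell lines, TPC-1 and K1, 24 h after transfection with siRNA against TRIM35 or with a negative control siRNA. Each of the 4 groups had 3 libraries, 12 in all. Per the labels' protocols, total RNA was extracted with TRIzol and cDNA was made by random-primed reverse transcription before adapter ligation and PCR. The labels name 1 batch for all 12 libraries, so no batch comparison was possible. The siRNA sequences, the strandedness of the libraries and the origin of the replicates (separate cultures or not) are not given in the sources used here, and p-values therefore measure only the spread between these libraries, which may be technical. The title of 1 TPC-1 control library gives another line name, whereas its other labels and its column name give TPC-1; it was kept in the TPC-1 control group.

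Per the submitters' processing notes, reads were trimmed with cutadapt 1.9.1 and the genome build was hg38; the aligner, the counting tool and the annotation release are not given in the sources used here. The authors deposited 1 table with raw read counts and FPKM values per gene and library for 61806 Ensembl genes. The deposited counts were whole numbers that summed to between 16705044 and 22928861 per library. The deposited FPKM values equal the counts divided by the exonic gene size and by the library's summed counts, since the total recovered from each FPKM column was 1 times the count sum in every library. Reads of overlapping genes on opposite strands cannot be told apart without stranded counting, and reads shared between near-identical copies may have been split in a way that is not given.

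The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, which left 17447 genes; the 44359 genes removed held between 0.0838% and 0.200% of a library's counts. Libraries were scaled by TMM. A quasi-likelihood model (glmQLFit, glmQLFTest) with 1 mean per group was fitted to all 12 libraries, so that the 4 groups shared the estimate of the spread with 8 residual degrees of freedom. The comparisons were TRIM35 siRNA against control siRNA in TPC-1, the same in K1, the difference between these effects (K1 minus TPC-1), and K1 against TPC-1 control libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were the absolute log2 fold change divided by the square root of the F statistic, and intervals are at 95%. Both forms of the test, edgeR for counts and limma on log2(FPKM + 0.1) for FPKM alone, had been written down before the data were examined; the file holds counts, so the limma form became an alternative. TRIM35 log2 CPM values, scaled by TMM, were also compared in each line by an exact two-sided permutation test, which with 3 against 3 libraries cannot go below 0.1.

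A total of 29 gene lists were fixed before the data were examined: apoptosis regulators, ATF4 stress response, autophagy and lysosome, cell adhesion and integrins, cholesterol synthesis, DNA replication, endothelial markers, epithelial genes, ER chaperones, fibroblast markers, glycolysis, heat shock, hypoxia, interferon-stimulated genes, invasion proteases, leukocyte markers, MAPK output, mesenchymal genes, mitochondrially encoded genes, mitosis, NF-kB inflammatory genes, NRF2 targets, oxidative phosphorylation, p53 targets, ribosomal proteins, RNAi machinery, TGF-beta and YAP targets, thyroid differentiation and the TRIM family. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 29 lists in each comparison. The rule for named genes, fixed at the same time, took TRIM35, up to 4 members of each list by adjusted p (all members for glycolysis), and the 12 called genes per direction with the largest change in each knockdown. It also took up to 8 genes per direction called in both lines, the 5 genes per direction with the smallest adjusted p for the difference, and the 6 called genes per direction with the largest change between control lines. Apart from the list rule, genes had to have a mean FPKM of at least 5 in the higher group, no overlap between the groups compared, a gene symbol and, by GENCODE 29, protein coding; the biotype and GC content were matched for 97.8% of the tested IDs. For the difference between lines the FPKM and overlap limits were not applied, and 1 gene that the rule takes there is not reported here.

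Where a gene had no count in 1 control group, its fold change is given as a lower bound against a floor of 3 counts over the group; where it had 1 to 3 counts, the ratio is given with its 95% Poisson interval. These intervals and floors cover counting error only, since reads were not marked with molecular identifiers. Replicate pairs were compared by a chi-square test over genes; its value per degree of freedom lay between 4.68 and 73.7, so no pair matched within sampling noise. The procedure was tested on simulated counts drawn from the real means and library sizes (17447 genes, 5 draws per line). For the TPC-1 comparison it recovered 15.2% of genes changed 1.5-fold, 57.6% of those changed 2-fold and 80.6% of those changed 4-fold, with 2.67% false calls. For the K1 comparison the shares were 14.9%, 61.5% and 83.9%, with 5.83% false calls. Each gene was drawn independently, so differences between libraries that many genes share were not simulated. The shares recovered and the false calls may therefore differ in the real libraries.

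Alternatives fixed before the data were examined were other pseudocounts, filters and scalings, library weights, limma without a trend, each line fitted alone, the replicate number as a block, a stricter threshold and leaving out each replicate in turn; the pseudocounts, quantile normalization, library weights and limma without a trend were run in the limma form on FPKM. DESeq2 1.42.0, the limma FPKM form in place of edgeR, no filter beyond 1 count, the first principal component as a covariate, the removal of the K1 control and siRNA libraries 3 together, and offsets for gene length and GC content were added after the data had been seen.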

Results

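The series profiled mRNA after knockdown of TRIM35, a tripartite motif protein of the E3 ubiquitin ligase family, in the papillary thyroid cancer lines TPC-1 and K1; its title names proliferation, metastasis and glycolysis as the processes of interest. Control and TRIM35 siRNA groups had 3 libraries each in either line. Library totals ran from 16705044 to 22928861 counts, and between 22526 and 28045 genes had at least 1 count. The comparisons below ask whether the targeted mRNA was lower, which genes and pathways differed between siRNA and control, whether the effect differed between lines, and how the lines differed without knockdown.

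TRIM35 (ENSG00000104228; hg38, chromosome 8, 27284886 to 27311272, minus strand) was expressed at a low level, and its mRNA in the siRNA libraries stayed close to control. In TPC-1, TRIM35 measured 2.86, 2.91 and 3.06 FPKM in the control libraries and 2.34, 2.56 and 2.58 FPKM in the siRNA libraries (means 2.94 ± 0.104 and 2.49 ± 0.133, SD, n = 3). In K1, it measured 1.51, 1.85 and 1.47 FPKM in control and 1.20, 1.49 and 1.53 FPKM in siRNA libraries (means 1.61 ± 0.209 and 1.41 ± 0.180, SD, n = 3). The siRNA level was 84.8% of control in TPC-1 (95% interval 66.8% to 108%, log2 fold change -0.24, SE 0.16) and 87.9% in K1 (68.5% to 113%, log2 fold change -0.19, SE 0.17). All 3 TPC-1 siRNA values lay below all 3 control values. On log2 CPM the exact permutation p was 0.1 in TPC-1, the smallest the design allows, and 0.5 in K1. Neither line passed the edgeR test (adjusted p = 1 in both), and the effects did not differ detectably between lines (difference 0.05, SE 0.23, adjusted p = 1.00). In the control libraries, K1 held 51.4% of the TPC-1 level (log2 fold change -0.96, SE 0.17, adjusted p = 9.46e-05). TRIM35 was covered by 85 to 244 counts per library.

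**Figure D1:**
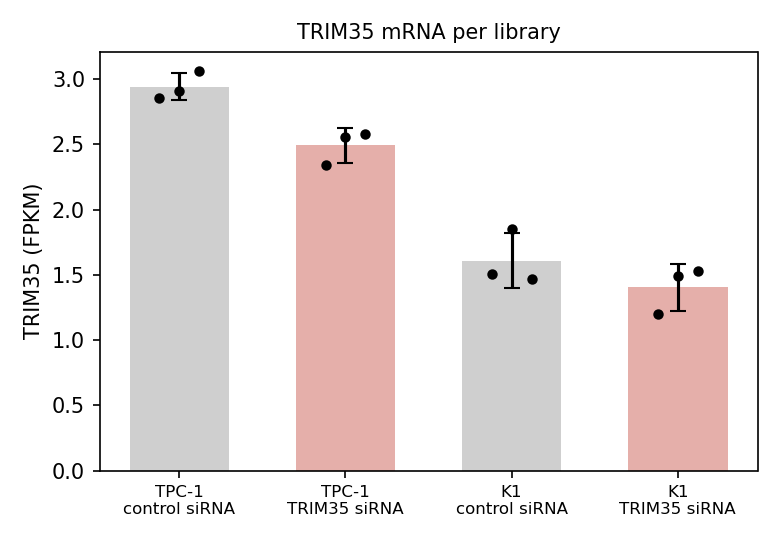
TRIM35 mRNA in FPKM (vertical axis, from 0) in each of the 12 libraries (points), with group means (bars) and SD (lines, n = 3 per group). The TPC-1 siRNA libraries lie at 2.34 to 2.58 FPKM against 2.86 to 3.06 FPKM in control, and the K1 groups overlap.

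In TPC-1, DNA replication genes were slightly lower and cholesterol synthesis and hypoxia genes slightly higher in the TRIM35 siRNA libraries by the preset-correlation list test, while glycolysis genes were centred on 0. None of these 3 calls held with an estimated correlation (adjusted p = 0.864 with an estimated correlation for DNA replication, and 0.585 for cholesterol synthesis and for hypoxia). The DNA replication list, which holds the MCM helicase subunits, had a median log2 fold change of -0.11 with 35 of 38 members below 0. MCM10 lay at -0.30 (SE 0.17) and MCM6 at -0.18 (SE 0.13); the list's adjusted p at the preset correlation was 2.59e-04. Cholesterol synthesis genes had a median of 0.12 with 20 of 24 above 0. INSIG1, a feedback regulator of sterol synthesis, lay at 0.37 (SE 0.15) and HMGCS1, the synthase upstream of mevalonate, at 0.30 (SE 0.12). The list's adjusted p at the preset correlation was 3.84e-04. Hypoxia genes had a median of 0.11 with 18 of 21 above 0, including the mitophagy receptors BNIP3L at 0.26 (SE 0.13) and BNIP3 at 0.29 (SE 0.19), with adjusted p = 0.00202 at the preset correlation. ATF4 stress genes had a median of -0.12 with 19 of 26 below 0, including asparagine synthetase, ASNS, at -0.48 (SE 0.29), with adjusted p = 0.0189, and adjusted p = 0.864 with an estimated correlation. ASNS did not reach 1 FPKM in 3 libraries, so it was absent from the limma fits on FPKM.

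Mitochondrially encoded genes (median 0.16, 13 of 13 above 0, adjusted p = 0.0420) and ribosomal protein genes (median 0.12, 27 of 29 above 0, adjusted p = 0.0491) also passed at the preset correlation in TPC-1, with adjusted p = 0.904 with an estimated correlation for both. The share of counts from mitochondrially encoded genes was 2.44% ± 0.619 in control and 2.76% ± 1.04 in siRNA libraries (SD, n = 3). Both calls were lost by limma on FPKM (medians 0.12 and 0.11; 0.00 and 0.04 with quantile normalization added), without a filter on low counts (0.17 and 0.13), with the first principal component as a covariate (-0.05 and 0.02) and with offsets for gene length and GC content (0.10 and 0.11). The fibroblast marker list was called higher (median 0.04 over 7 members, adjusted p = 0.0207; adjusted p = 0.495 with an estimated correlation). DCN, the proteoglycan decorin, had 0 counts in the 3 control libraries and 9 to 12 in the siRNA libraries. It was the 1 member called when adjusted over the list alone, there and in the mesenchymal list. At the preset correlation the call for hypoxia held whichever library was left out. The DNA replication call was lost without siRNA library 1 (median 0.02) or control library 2 (-0.07), and the cholesterol call without control library 1 (0.09) or siRNA library 3 (0.08). The ATF4 call was lost without control library 1 (-0.08) or 2 (-0.07) or siRNA library 1 (-0.05) or 3 (-0.11). The fibroblast call was lost without control library 1 (0.28), 2 (0.12) or 3 (0.13) or siRNA library 1 (0.01) or 3 (0.20). The mitochondrial call was lost without control library 2 (0.12) or 3 (0.03) or siRNA library 1 (-0.16) or 2 (0.22), or K1 control library 2 (0.18) or K1 siRNA library 3 (0.18). The ribosomal call was lost without control library 3 (0.02) or siRNA library 1 (0.06) or 2 (0.03), or K1 control library 2 (0.14) or K1 siRNA library 2 (0.12). It was also lost with the replicate number as a block (0.11, adjusted p = 0.0711 at the preset correlation).

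The glycolysis list had a median of 0.00 in TPC-1, with 12 of 24 members above 0 and 12 below, and did not pass (adjusted p = 0.846; mean -0.02). SLC2A3, a glucose transporter, had the smallest p of the list at 0.83 (SE 0.21), followed by the aldolase ALDOC at -1.28 (SE 0.49); adjusted over the list alone these gave adjusted p = 0.0805 and 0.236, and 0 members passed by either adjustment, by edgeR. Over 28 alternatives the SLC2A3 value ranged from 0.10 to 0.95 and was called in 0. ALDOC did not reach 1 FPKM in 3 libraries, so it was absent from the limma fits on FPKM. HK2, LDHA and SLC2A1 lay at -0.08 (SE 0.14), 0.10 (SE 0.18) and 0.03 (SE 0.14). Mitosis genes had a median of -0.02 (adjusted p = 0.807), mesenchymal genes 0.02 (0.335), epithelial genes 0.01 (0.807) and invasion proteases -0.04 (0.612). The 22 lists without a call had medians between -0.26 for leukocyte markers and 0.13 for thyroid differentiation. In the autophagy, epithelial, glycolysis, heat shock, interferon, NRF2 and TRIM family lists, none called, the median, the mean and the test differed in sign.

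By gene, edgeR called 0 of 17447 genes in TPC-1, with 337 at an unadjusted p under 0.05 against 872 expected by chance and a smallest adjusted p of 0.146. DESeq2 called 2, DCN and SULF1, an extracellular sulfatase with 0 counts in the control and 21 to 24 in the siRNA libraries; limma on FPKM called 0. The rule for named genes gave no gene here beyond TRIM35 and list members, so SULF1 was chosen after its values were seen. Among 6177 genes with a mean FPKM of at least 5 in TPC-1, 6115 (99.0%) had a 95% interval that lay within a 2-fold change in either direction.

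In K1, mitosis genes were slightly lower in the TRIM35 siRNA libraries by the preset-correlation test. The list had a median log2 fold change of -0.11 with 29 of 34 members below 0, adjusted p = 1.27e-04, and adjusted p = 0.992 with an estimated correlation. The spindle protein NUSAP1 lay at -0.72 (SE 0.35), CCNB2, a cyclin, at -0.20 (SE 0.11), the phosphatase CDC25C at -0.33 (SE 0.20) and the kinase CDK1 at -0.20 (SE 0.14). By library, the mean log2 level of the list lay at 0.13, 0.0033 and -0.14 in control libraries 1, 2 and 3 and at -0.23, -0.19 and 0.065 in siRNA libraries 1, 2 and 3 relative to the control mean, so that it also moved with the first principal component of K1, on which control library 1 and siRNA library 3 lie at one end and control library 3 and siRNA library 1 at the other. The call was lost without control library 1 (median -0.05) or siRNA library 1 (-0.06) or 2 (-0.06), and was kept with that component as a covariate. Glycolysis genes had a median of -0.05 with 17 of 24 below 0 and did not pass (adjusted p = 0.378); ENO2 lay at -0.12 (SE 0.11), GPI at -0.14 (SE 0.13) and LDHA at -0.09 (SE 0.18), and 0 members passed adjusted over the list alone. Without the K1 control and siRNA libraries 3, left out after the data had been seen, 8 lists passed at the preset correlation, among them ribosomal proteins (median -0.48), oxidative phosphorylation (-0.42) and glycolysis (-0.13, adjusted p = 0.0279); an estimated correlation was not run there.

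DNA replication genes in K1 had a median of -0.08 (adjusted p = 0.357), mesenchymal genes 0.03 (0.422), epithelial genes -0.01 (0.986) and invasion proteases -0.01 (0.986). The 28 lists without a call had medians from -0.12 for leukocyte markers to 0.24 for fibroblast markers, and the smallest adjusted p among them was 0.0589, for cell adhesion and integrins. In 8 of them (apoptosis regulators, ATF4, epithelial, ER chaperones, heat shock, NRF2, p53 and thyroid differentiation) the median, the mean and the test differed in sign. EdgeR called 0 of 17447 genes in K1, with 136 at an unadjusted p under 0.05 and a smallest adjusted p of 1; DESeq2 and limma on FPKM also called 0. Without a filter on low counts edgeR called 2, CASP14 higher and SLIT1 lower, which were chosen after their values were seen. Among 6268 genes with a mean FPKM of at least 5 in K1, 6175 (98.5%) had a 95% interval within a 2-fold change in either direction.

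**Figure D2:**
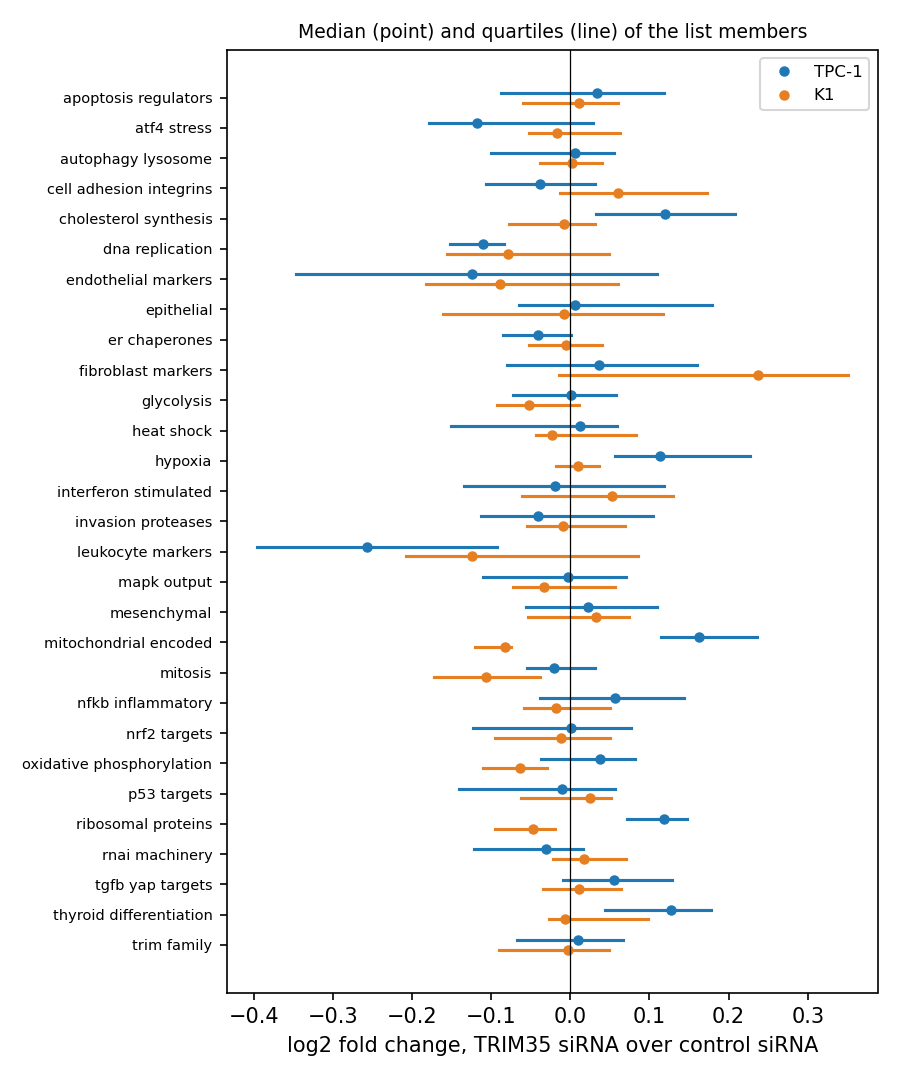
Median (point) and quartiles (line) of the members' log2 fold change, TRIM35 siRNA over control siRNA (horizontal axis), for each of the 29 gene lists (vertical axis) in TPC-1 (blue) and K1 (orange). Most medians lie within 0.2 of 0; DNA replication has -0.11 in TPC-1 and -0.08 in K1, and mitosis -0.02 and -0.11.

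The knockdown effects of the lines were compared directly. Ribosomal protein genes (median difference, K1 minus TPC-1, -0.17), mitochondrially encoded genes (-0.29), cholesterol synthesis (-0.15), hypoxia (-0.15) and mitosis (-0.09) were lower, and ATF4 stress (0.12) and adhesion genes (0.09) higher, by the preset-correlation test. For none of the 7 did the call hold with an estimated correlation (adjusted p = 0.821 with an estimated correlation for each). The number of called lists was 2 without TPC-1 control library 1, TPC-1 siRNA library 1 or K1 siRNA library 1, 3 without K1 control library 1, and 4 without TPC-1 control library 2 or 3, TPC-1 siRNA library 2 or 3, K1 control library 2 or K1 siRNA library 2. By limma on FPKM the adhesion (0.090) and mitochondrial (-0.25) calls were lost, with quantile normalization added also the ATF4 call (0.12), and with library weights the ATF4 (0.12), cholesterol (-0.072) and hypoxia (-0.081) calls. With offsets for gene length and GC content the adhesion (0.081), mitochondrial (-0.18) and ribosomal (-0.12) calls were lost, and without both K1 libraries 3 the ATF4 (-0.051) and mitochondrial (-0.33) calls. The mitochondrial median was 0.01 without TPC-1 siRNA library 1, and the ribosomal one 0.01 without K1 control library 1. The ATF4 median was 0.014 without K1 siRNA library 3, and the adhesion one 0.021 without TPC-1 control library 3. Without K1 siRNA library 1 the mitosis median was -0.034. Each of these calls was lost there. The cholesterol and hypoxia calls were lost without TPC-1 control library 1 (-0.12 each), among others. The 22 lists without a call had medians from -0.10 for oxidative phosphorylation to 0.29 for leukocyte markers; in the epithelial, fibroblast, invasion protease, MAPK, mesenchymal and NRF2 lists the median, the mean and the test differed in sign. DCN was the 1 member called, lower, adjusted over the list alone in the fibroblast and the mesenchymal list. EdgeR called 0 genes for the difference, with 301 at an unadjusted p under 0.05; DESeq2 called SLIT1 and SULF1, and limma on FPKM called 0. By edgeR, SLIT1, a secreted axon guidance protein, and SULF1 both had an adjusted p of 0.0700, and DCN 0.510; of the other genes the rule names, GASK1B, COL8A2, MPP4, ADAD2, UCA1 and ANXA10 had an adjusted p of 1.00. No gene was called in both lines, so the overlap of calls was 0. Across 17447 genes, which are not independent replicates, the fold changes of the lines had a Pearson r of -0.04 and a Spearman rho of -0.07, and 45.6% had the same sign. Among the 6427 genes with a mean FPKM of at least 5 the values were -0.08, -0.16 and 43.6%. The lines share no library.

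The largest differences lay between the lines themselves. K1 control libraries expressed mitosis and DNA replication genes at a lower and NF-kB inflammatory, invasion protease and mesenchymal genes at a higher level than TPC-1 control libraries. All 34 mitosis genes were called lower in K1, with a median log2 fold change of -2.67, a 6.37-fold difference; CCNA2 (cyclin A) lay at -3.30 (SE 0.14) and the kinase AURKB at -3.11 (SE 0.15). Of 38 DNA replication genes, 37 were called lower (median -2.78), with MCM10 at -5.05 (SE 0.21) and UHRF1, which links replication to maintenance methylation, at -3.65 (SE 0.15). Of 31 NF-kB inflammatory genes, 26 were called higher and 1 lower (median 3.36), among them the cytokines IL24 at 9.57 (SE 0.20), IL1A at 8.80 (SE 0.20) and IL1B at 8.60 (SE 0.24).

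Invasion proteases (median 0.91, 15 of 25 called higher and 6 lower) included the matrix metalloproteinases MMP1 at 9.67 (SE 0.23) and MMP3 at 9.43 (SE 0.23), and mesenchymal genes (median 1.54, 18 of 24 higher and 3 lower) the collagens COL6A3 at 7.97 (SE 0.28) and COL5A2 at 4.23 (SE 0.15). These 5 lists passed with an estimated correlation too (adjusted p = 0.0418 for mitosis, NF-kB, invasion proteases and mesenchymal genes, 0.0469 for DNA replication). The counts of called members were the same when adjusted over the list alone.

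The 6 lists that follow passed camera at the preset correlation but not with an estimated one; fry, which does not compare a list with other genes, called all 6. Glycolysis genes had a median of -0.76 in K1, with 18 of 24 called lower and 3 higher. Hexokinase HK2 lay at -3.91 (SE 0.16), the transporter SLC2A1 at -2.65 (SE 0.15), lactate dehydrogenase LDHA at -2.44 (SE 0.19) and SLC2A3 at 8.28 (SE 0.17). The list had adjusted p = 0.548 with an estimated correlation, and the call was lost among genes at FPKM of at least 5 (median -0.53, adjusted p = 0.0719). ATF4 stress genes (median -1.01, 18 of 26 lower, 4 higher) included the transporter SLC7A5 at -4.62 (SE 0.13), with adjusted p = 0.263 with an estimated correlation, and cholesterol synthesis genes (-0.49, 14 of 24 lower; 13 adjusted over the list alone) had adjusted p = 0.548 with an estimated correlation. Thyroid differentiation genes (1.58, 7 of 9 higher, 2 lower) included the thyroid transcription factors PAX8 at 2.46 (SE 0.12) and FOXE1 at 3.01 (SE 0.15), with adjusted p = 0.430 with an estimated correlation. The filter on low counts left 9 of 20 thyroid differentiation, 7 of 10 fibroblast and 7 of 17 leukocyte list members, and the counts here cover those alone. Fibroblast markers (4.03, 5 of 7 higher, 1 lower) and leukocyte markers (1.40, 5 of 7 higher, 1 lower) had adjusted p = 0.121 and 0.313 with an estimated correlation. Among them were FAP, with 1 count in TPC-1 and 1104 in K1 control libraries (ratio 971, 95% Poisson interval 174 to 38396), and LCP1, an actin-bundling protein, at 5.80 (SE 0.20). The cholesterol and thyroid calls were lost without TPC-1 control library 2 (medians -0.47 and 1.38) or K1 control library 3 (-0.45 and 1.5). The cholesterol call was also lost at FPKM of at least 5 (-0.44) and by limma on FPKM with quantile normalization (-0.36), and the thyroid call in all 6 limma fits on FPKM (1.03 to 1.38), without both K1 libraries 3 (1.5) and with offsets for gene length and GC content (1.59). The leukocyte call was lost without TPC-1 control library 1 (1.46), K1 control library 3 (1.36) or K1 siRNA library 1, 2 or 3 (1.30 each), without both K1 libraries 3 (1.36), and without a filter on low counts (0.58).

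The remaining 18 lists were not called between the control lines by camera at either correlation, although fry called 12 of them. The medians above 0 were 0.59 for MAPK output, 0.33 for p53 targets, 0.29 for autophagy and lysosome, 0.23 for adhesion and integrins, 0.15 for apoptosis regulators, 0.10 for endothelial markers, 0.08 for the TRIM family and 0.04 for ER chaperones. Those below 0 were -0.01 for mitochondrially encoded genes, -0.14 for RNAi machinery, -0.23 for ribosomal proteins, -0.32 for epithelial genes, -0.38 for oxidative phosphorylation, -0.41 for hypoxia, -0.43 for TGF-beta and YAP targets, -0.48 for interferon-stimulated genes, -0.66 for NRF2 targets and -0.87 for heat shock. For apoptosis regulators, epithelial, hypoxia and mitochondrially encoded genes the median, the mean and the test differed in sign.

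**Figure D3:**
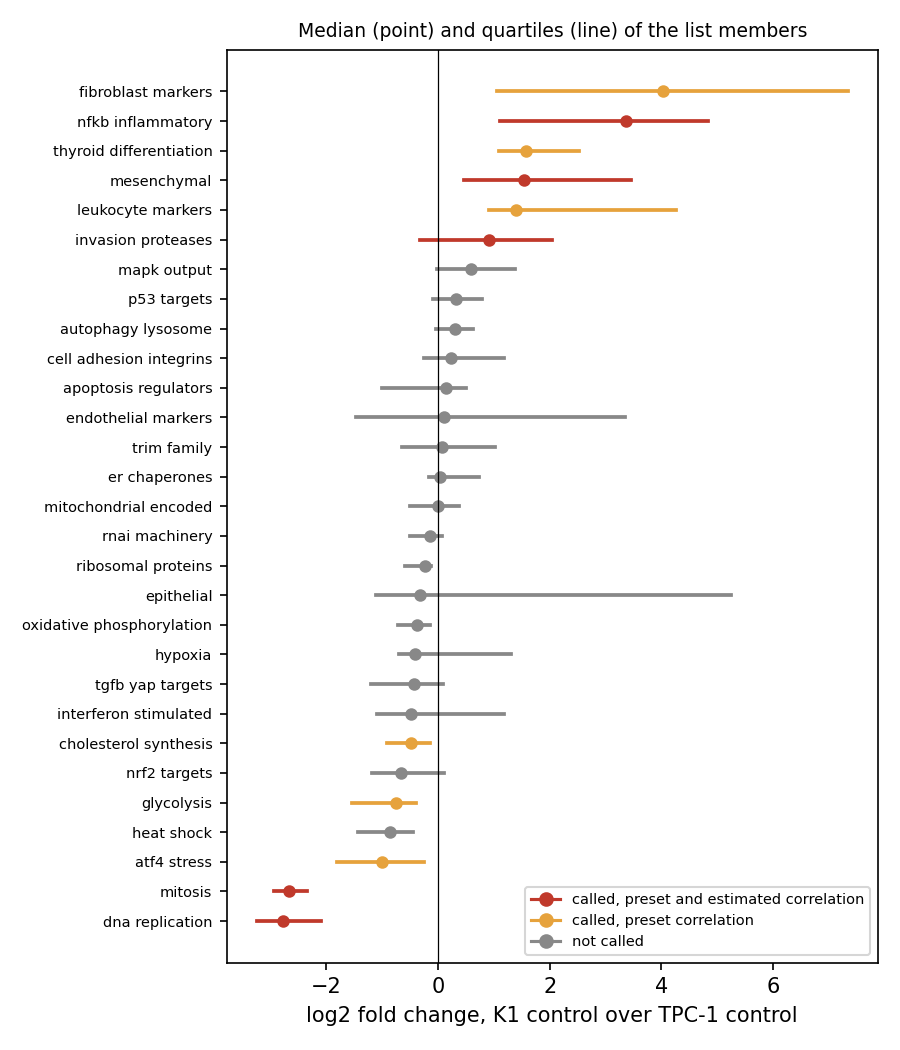
Median (point) and quartiles (line) of the members' log2 fold change, K1 control over TPC-1 control (horizontal axis), for each of the 29 gene lists (vertical axis); red marks lists called with the preset and the estimated correlation, orange those called by camera with the preset but not the estimated correlation. DNA replication (-2.78) and mitosis (-2.67) lie lowest, fibroblast markers (4.03) and NF-kB inflammatory genes (3.36) highest.

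By gene, edgeR called 11853 of 17447 genes between the control lines (67.9%), 6250 higher and 5603 lower in K1; 4530 and 3056 of them differed at least 2-fold and 1182 and 394 at least 16-fold. The genes with the largest rise by the fixed rule were FOXD1, a forkhead transcription factor (at least 875-fold higher), the membrane glycoprotein CD200 (at least 530-fold), CFAP300 (at least 334-fold), the homeobox gene MEOX1 (at least 297-fold) and BEX2 (at least 220-fold), all with 0 counts in the TPC-1 control libraries. CSF3, granulocyte colony-stimulating factor, measured 273 FPKM against 0.160 FPKM (SD 47.9 and 0.0529, n = 3). The falls the same rule took, ordered by the fitted log2 fold change, began with CDKN2A, a cell cycle inhibitor locus, with 3755 counts in TPC-1 and 1 in K1 control libraries (ratio 4268, 95% Poisson interval 766 to 168630). MTAP, methylthioadenosine phosphorylase, measured 7.50 ± 0.614 FPKM in TPC-1 (SD, n = 3), HAVCR1 62.8 ± 12.6, SCARA3 22.0 ± 2.02 and EEF1A2 25.6 ± 4.11, with 5, 15, 6 and 9 counts in all in the K1 control libraries. Their ratios were 1354 (95% Poisson interval 580 to 4173), 1262 (765 to 2255), 919 (422 to 2505) and 849.7 (447 to 1859). LRRC61 had 0 counts in the K1 control libraries, so its fall is known only as at least 208-fold. All of these genes passed the edgeR test, with CSF3 at adjusted p = 1.08e-13 and CDKN2A at adjusted p = 3.30e-12. FN1, fibronectin, took between 4.28% and 6.50% of the counts in K1 libraries and between 0.171% and 0.282% in TPC-1 libraries.

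The libraries of 1 group differed from each other along a principal component that did not separate the treatments. The first component held 39.0% of the variance in TPC-1 and 54.3% in K1. In TPC-1 it followed the replicate number. Control libraries 1, 2 and 3 lay at 25.6, -9.50 and -34.8, and siRNA libraries 1, 2 and 3 at 39.5, 11.2 and -32.0. Each siRNA library thus lay above the control library of the same number. In K1, control library 1 and siRNA library 3 lay at one end (32.8 and 49.5) and control library 3 and siRNA library 1 at the other (-26.2 and -32.3). The share of counts from the ribosomal protein list followed it, at 2.94% and 3.00% in the first pair and 2.04% and 1.92% in the second.

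**Figure D4:**
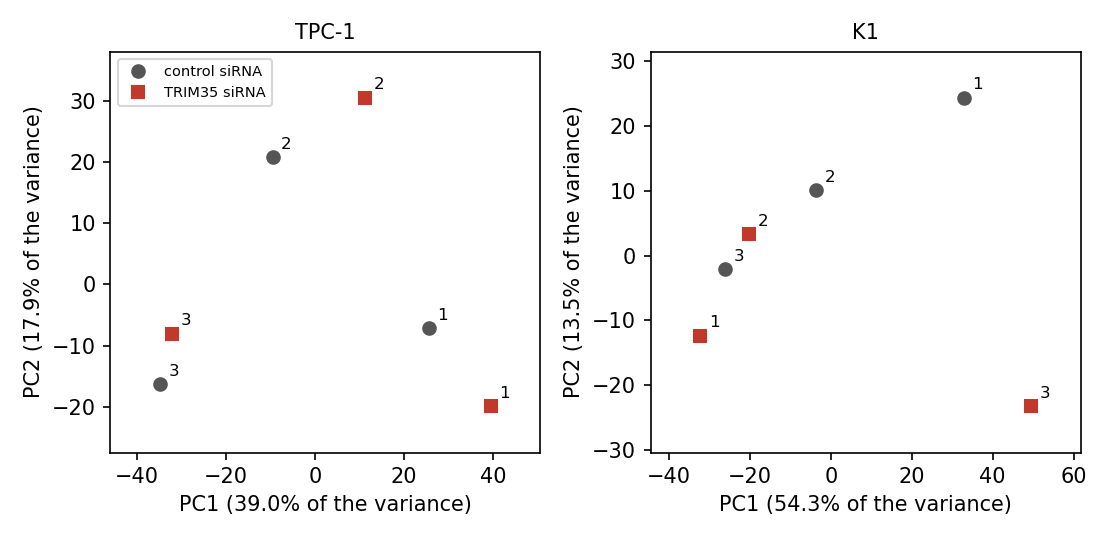
First and second principal component scores of log2 CPM in TPC-1 (left) and K1 (right); grey circles are control siRNA and red squares TRIM35 siRNA libraries, numbered by replicate. The treatments do not separate along the first component, which holds 39.0% of the variance in TPC-1 and 54.3% in K1.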

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

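The tests of the difference between the lines were fixed before the data were examined; the carry-over and shared-rise tests were chosen after the counts had been seen. Several forms of the rule that picks the genes with few counts, and of the bound for the shared-rise test, were also weighed after those counts had been seen.

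A total of 7 gene lists differed between the lines in their response by the interaction test at the preset correlation: ATF4 stress (0.12) and adhesion and integrins (0.093) were higher in K1 minus TPC-1, and cholesterol synthesis (-0.15), hypoxia (-0.15), mitochondrially encoded genes (-0.29), mitosis (-0.094) and ribosomal proteins (-0.17) lower. None held with an estimated correlation. SLIT1 (-7.02), SULF1 (-10.98) and COL8A2 (-3.41) stood out because the siRNA libraries lay on one side of the controls in TPC-1 and on the other side in K1, relative to library totals; for SULF1 the K1 control and siRNA libraries 3 both had 1 count, so that its K1 groups were parted by library total alone. Their edgeR adjusted p for the difference was 0.0700, 0.0700 and 1.00, and the fitted values of SLIT1 and SULF1 rest on groups with few counts, so they depend on the prior count.

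SLIT1 and SULF1 belong to a set of 8 genes with at most 2 counts in each TPC-1 control library and at least 5 in each TPC-1 siRNA library, the lowest of these also at least 2 times the highest control count plus 4: DCN, MAP2, ITIH5, APLNR, SULF1, SLIT1, DCC and NEFL; 0 genes showed the opposite. In K1 the same rule took 5 genes, CASP14 higher and LRP2, SLIT1, LINC01725 and CAMTA1-DT lower in the siRNA libraries; in each line the other splits of the 6 libraries gave at most 3 in both directions together, and 10 splits are too few for a share under 0.05. Carry-over from the K1 libraries is argued against: the 8 genes would need a median of 440% K1 RNA (smallest 20.7%), whereas 30 K1 marker genes rose by 0.00717% of their K1 level. A rise shared by both lines stays open for the set: by edgeR without a filter on low counts, adjusted over the 8 genes, 3 (SULF1, SLIT1 and DCC) were called lower in K1 siRNA libraries and 0 higher, while the other 5 were not called, with DCN, MAP2 and APLNR above 0. RNA from a source outside the series was not tested, and a response that differs between the lines also stays open, with SLIT1 and SULF1 at an edgeR adjusted p of 0.0700 for the difference.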

How the results depend on the processing

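Over the alternatives run, 29 for the knockdown comparisons, calls stayed between 0 and 2 genes in TPC-1, and in K1 between 0 and 2 apart from library weights. The control line difference ranged from 5330 to 13101 calls, and no gene was called in both lines under any alternative. List values kept their side of the threshold in 750 of 811 cases in TPC-1, 782 of 817 in K1, 669 of 759 for the difference and 668 of 730 between controls. Most cases are lists that the main test did not call. Its calls were lost in 57, 5, 76 and 29 cases, in that order. In TPC-1 the call was kept in 11 of 29 alternatives for mitochondrially encoded genes, the least stable, and 27 of 29 for hypoxia, the most. The 2 that lost hypoxia were the estimated correlation and fry. All other list alternatives kept the preset correlation, so their number cannot test it. Those that leave out a K1 library also keep every TPC-1 library. For the difference it was kept in 12 of 27 for mitochondrially encoded and adhesion genes, and in 20 of 27 for cholesterol synthesis. The limma FPKM form, no filter beyond 1 count, the principal component, the removal of both K1 libraries 3, the offsets and DESeq2 were chosen after the data had been seen. Except where stated, the cause of a change was not tested.

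Calls in TPC-1 were 1 with a pseudocount of 0.01, 2 without a filter on FPKM or beyond 1 count, 1 with the principal component and 2 by DESeq2. Calls in K1 were 2 without either filter and 2 with the principal component. For the difference they were 4 without either filter and 2 by DESeq2. The control line difference fell to 5330 at FPKM of at least 5, where 7525 genes were tested, and to 7586 with the added 2-fold threshold, both by construction. Library weights gave 9475 calls in K1, 980 for the difference and a called TRIM35 value of -0.30 in K1, and turned ENO2 in K1 from -0.12 to 0.094; these weights were 65.9 and 23.2 for the K1 control and siRNA libraries 2 against 0.180 to 2.54 for the others, so the fit rests on 1 library per group.

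Pseudocounts, quantile normalization, no trend and library weights were run in the limma form on FPKM, over 13630 genes. Called lists in TPC-1, 7 by the main test, were 4 by limma on FPKM itself, with its pseudocount at 0.01, quantile normalization or no trend, 5 with its pseudocount at 1 and 7 with library weights. The limma form changes the test, the input and the filter together, and in it and with the principal component (4) the fibroblast list had too few members to be tested. Called lists in TPC-1 were 0 with an estimated correlation and with fry. In K1, 1 by the main test, they were 2 at FPKM of at least 5, with median-ratio scaling and with each line fitted alone, 6 with library weights, 5 with the principal component, 8 without both libraries 3, and 0 with an estimated correlation and with fry. For the difference, 7 by the main test, they were 4 with quantile normalization and 0 with an estimated correlation and with fry. For the control lines, 11 by the main test, they were 6 at FPKM of at least 5, where 3 of the 11 were not tested, 5 with an estimated correlation and 23 with fry.

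Leaving out 1 replicate gave 0 calls in either line, 0 to 1 for the difference (SLIT1 without TPC-1 siRNA library 3, SULF1 without K1 control library 3) and 10953 to 12513 between controls. Called lists ranged from 2 to 7 in TPC-1, 0 to 5 in K1, 2 to 8 for the difference and 8 to 12 between controls; TRIM35 ranged from -0.27 to -0.16 in TPC-1 and from -0.29 to -0.06 in K1 (-0.37 without both K1 libraries 3). Same-numbered control and siRNA libraries correlated at 0.38, 0.09 and 0.41 in TPC-1, where every library correlated best with its own number, a hint of pairing from the data although 1 value was under 0.1. In K1 they correlated at -0.49, 0.09 and -0.53, and the libraries did not; the numbers were not taken as pairs. With the replicate block edgeR called 0 genes in TPC-1 (343 at an unadjusted p under 0.05), 0 in K1 (126) and 0 for the difference (299), and 6, 1 and 7 lists; the control lines have no such fit. TRIM35 was not tested at FPKM of at least 5. At these library sizes and 3 libraries per group, 15.2% of simulated 1.5-fold changes were recovered in TPC-1, with genes drawn independently. Other depths and differences between libraries that many genes share were not simulated.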

Other observations

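The tests of chromosome 9, of the other splits, of TRIM35, of gene length and GC content and of exchanged libraries were all chosen after the results they bear on had been seen.

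Several genes outside the fixed lists separated the lines; apart from MTAP and CDKN2A, which the naming rule took, they were chosen after their values were seen. CCDC6 had 21 counts in TPC-1 and 6263 in K1 control libraries, and RET, a receptor tyrosine kinase, 2284 and 46 counts. TPC-1 is known to carry a CCDC6-RET rearrangement, which counts per gene do not resolve. MTAP, CDKN2A, CDKN2B and DMRTA1, neighbours on chromosome 9 (hg38, 21802636 to 22455740, 653 kb), were near 0 in K1, whereas IFNE and ELAVL2 on either side were expressed there (9.24 and 3.98 FPKM in control libraries).

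A hypothesis is that the stretch on chromosome 9 may be lost or silenced as a whole in K1. In a first test, the run of 4 neighbouring protein-coding genes under a hundredth of the TPC-1 count was as long as the longest run in 2000 shuffles of the gene order (1 shuffle as long, permutation p = 0.001), which did not meet the bound set for it. A second test took all 16 genes of the stretch, which held 20 counts in K1 and 26002 in TPC-1 (0.0754%), and the last test took the 12 genes not used to find the run, which held 2 and 1856 counts (0.106%, 95% Poisson interval 0.0128% to 0.382%). For comparison, 5 TPC-1 marker genes that were near 0 in the K1 control libraries held 0.118% of their TPC-1 level in the K1 siRNA libraries. The interval extends beyond 2 times this share, so 2 counts are too few to decide, and several of the 12 genes overlap the chosen 4. Gene counts cannot separate loss from silencing, and 2 other runs of 3 genes near 0 in K1 exist (TRIM58, OR2W3 and OR2T8; ZNF682, ZNF90 and ZNF486).

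TRIM35 mRNA in the siRNA libraries lay close to control. Too few reads to see a halving is argued against by the lower 95% bounds, 66.8% of control in TPC-1 and 68.5% in K1. An exchange of libraries within a line that hides a halving is argued against too. Over the 10 splits of the 6 libraries, the largest contrast left TRIM35 at 84.7% in TPC-1, in the real split. In K1 it left TRIM35 at 79.4%, in the split that exchanges control and siRNA libraries 3. Whether libraries were exchanged at all is not decided by these values. An mRNA fall that had recovered or not yet occurred at 24 h, an effect on protein alone and an inactive siRNA stay open and were not tested.

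In each line 1 other split of the 6 libraries called genes, whereas the real one called none. In TPC-1 the real split gave 0 and the highest other 1012; in K1 the values were 0 and 947; 10 splits are too few for a share under 0.05. All 10 splits in each line, and for the difference all 60 drawn (real 0, highest other 2262), gave at least the real count, as they must when it is 0, so these comparisons decide nothing about chance. For the control lines the real split, with 11853 calls, was the 1 of 10 that called any gene (highest other 0), and 10 splits are again too few for a share under 0.05. Counts this far above the real one point to a structure among libraries of 1 group.

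For that structure, gene length and GC content as the whole cause are argued against in TPC-1, where 88.1% of the median fold change of the strongest other split was left after the correction (0.54 to 0.48, SE 0.13 to 0.11) and 1344 genes were called. In K1, 72.3% was left (0.56 to 0.41, SE 0.14 to 0.12) but calls went from 947 to 1, because the fold shrank more than its SE. The rule for reading this was changed after the value was seen, and the question stays open in K1. Across 13635 genes, the loadings of the first component correlated with gene length at a Spearman rho of -0.30 in TPC-1 and -0.45 in K1. For GC content the values were 0.17 and 0.13. A partial role of gene length thus stays open in both lines. The K1 split with 947 calls is the real one with control and siRNA libraries 3 exchanged. Of 5 genes chosen in libraries 1 and 2, 2 followed the labels given (exact binomial p = 1). With 5 genes this test cannot go under 0.05, so it could not decide, and it leaves out the size of the differences. In control and siRNA libraries 3, the 2 genes had 15 and 0 counts (SLIT1) and 5 and 9 (ATXN7L3-AS1). The other 3 had 4 and 1, 8 and 6, and 1 and 1, the last placed by library total alone. DCC, chosen in TPC-1, followed the labels too (6 and 0 counts in libraries 3), as did CASP14, LRP2, LINC01725 and CAMTA1-DT, which had been chosen with library 3. No biological explanation was tested.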
